A study of Mus musculus with 4 samples.

How the data were processed

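Messenger RNA was selected by its poly(A) tail and made into strand-marking libraries with a directional kit, per the labels' protocols. There were 4 libraries, 2 of Lgr5-EGFP-positive, CD24-negative cells from small intestine (SISC) and 2 of Lgr5-EGFP-positive cells from large intestine (LISC). Groups and replicate numbers were taken from the sample titles. STAR 2.7.2b, RSEM 1.2.31 and the mouse build GRCm38 (mm10) are named in the submitters' processing notes. The annotation release, the strand setting of the counting and any trimming are not given in the sources used here.

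The authors deposited RSEM's gene-level expected counts, in which reads that fit several genes are divided among them by estimated abundance, so that values need not be whole (7.25% of genes had a value more than 0.001 from a whole number in at least 1 library). The deposited TPM values are scaled by each gene's effective length, and the deposited gene lengths and effective lengths served only for a fragment length check, given as the median of length minus effective length: 312 and 180 bases in SISC replicates 1 and 2, and 236 and 178 bases in LISC replicates 1 and 2. RSEM's division of reads can blur close copies such as the alpha-defensin, gasdermin C, Cyp2c and Hsd3b genes. The count of rRNA depends on how well the poly(A) selection removed it, and it differed strongly between replicate numbers, which lowers the depth left for other genes in replicate 1. Log2 ratios of LISC over SISC within a replicate number are given for the called genes as a whole, for the gene lists and for some genes for that reason.

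Gene identifiers were matched to the GENCODE vM21 annotation of GRCm38: 55141 of 55487 had a symbol there and 346 did not. Coordinates are 1-based and from that annotation. Expected counts were rounded to whole numbers. Totals per library ran from 12795400 to 27227700, where 3 counts, the limit that a count of 0 allows, correspond to 0.0937 to 0.278 CPM. Replicates of a group differed far beyond counting noise (chi-square per degree of freedom of 914 in SISC and 848 in LISC over genes with a summed count of at least 20), so that no library was counted as a copy of another. Correlations of log CPM across genes, which are not independent replicates, were 0.915 between SISC replicates, 0.922 between LISC replicates, 0.880 between the replicate 1 libraries and 0.882 between the replicate 2 libraries. The first principal component (56.9% of variance) parted the groups and the second (35.6%) the replicate numbers.

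The main comparison was LISC over SISC, fitted in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit and test, group as the only term, TMM factors, filterByExpr with its minimum count of 10), with Benjamini-Hochberg adjustment over the 14165 genes kept and a threshold of 0.05. Standard errors are approximate, the log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, as mean ± SD over 2 libraries or as each library's value. Where a group had 0 counts, the fold is a lower bound against 3 counts per library, and where it had 1 to 3 counts, a ratio of pooled counts with its exact 95% interval. Both cover counting error only, as reads are not independent molecules.

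Before the data were examined, 24 gene lists, a symbol pattern for transcription factor genes and the rule for named genes were fixed from general knowledge of the intestinal epithelium. None of the lists was chosen on these samples. Lists with at least 5 tested genes were tested with camera and fry in limma 3.58.1, on log CPM with a prior count of 2. Camera used a preset correlation of 0.01 and was repeated with an estimated one, each adjusted over the lists by Benjamini-Hochberg. The rule named the 10 called genes with the largest fold change in each direction at a mean TPM of at least 10 in the higher group, up to 4 called members per list at a TPM of at least 1, the 8 called factor genes with the largest change per direction at a TPM of at least 5, and Lgr5 and Cd24a. Other genes given with values (among them Mptx1, Etv5, Car4, Scnn1a, Itln1 and list members that missed the threshold) were chosen after their values were seen.

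The fits were tested on simulated counts with 200 genes changed between LISC and SISC. Without a difference between replicate numbers (13805 genes), edgeR recovered 52% of 2-fold, 94% of 4-fold and 100% of 8-fold and 16-fold changes, with 24 of 197 calls on unchanged genes. With the real difference between replicate numbers kept (13829 genes), edgeR called 0 genes, DESeq2 recovered 2%, 80%, 100% and 100% of these sizes with 3 of 144 calls on unchanged genes (14165 genes), and a block on replicate number recovered 66%, 100%, 100% and 100% with 35 of 218 calls on unchanged genes. On that simulation camera gave a raised list of 20 genes a p of 6.06e-14 with the preset and 0.0146 with an estimated correlation. Of 200 unchanged lists, 3 and 0 had a camera p below 0.05. These lists held randomly picked genes simulated independently. The check therefore cannot show how the preset fares for lists of correlated genes, such as the enteroendocrine markers (estimated correlation 0.774).

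Alternatives were DESeq2 1.42.0 (Wald test), limma-trend on log2(TPM + 1) for genes with a mean TPM of at least 1, DESeq2's size factors and upper-quartile factors in the edgeR fit, no filter on low counts, a stricter filter (CPM of at least 1 in 2 libraries), a test against a fold of 2, the replicate number as a block, and leaving out each library in turn. Leaving out the nuclear rRNA gene and all mitochondrial genes was added after seeing the data. Closing tests used Python 3.11.15 with scipy 1.17.1.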

Results

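RNA was sequenced from stem cells of the mouse intestine, sorted from crypts of Lgr5-EGFP-IRES-creERT2 mice aged 6 to 12 weeks. In these mice the stem cell gene Lgr5 drives a green fluorescent reporter. Small-intestinal stem cells (SISC) were sorted as reporter-positive and CD24-negative, and large-intestinal stem cells (LISC) as reporter-positive, with no CD24 gate named for them. Each of the 2 groups held 2 libraries. Expected counts were given for 55487 genes, and their totals were 16490500 and 27227700 in SISC replicates 1 and 2 and 12795400 and 24142200 in LISC replicates 1 and 2. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical, except that sex-linked genes place the 2 SISC libraries in animals of different sex.

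Lgr5, the gene that marks the sorted cells, was read at 114 and 173 CPM (counts scaled to library size with TMM factors) in the SISC libraries and at 147 and 89.7 CPM in the LISC libraries, a log2 difference of −0.28 ± 0.40 (SE) that did not pass edgeR's quasi-likelihood test (adjusted p = 0.957). Cd24a, which encodes the surface protein used to gate SISC only, was read at 341 and 407 CPM in SISC and 328 and 503 CPM in LISC, a log2 difference of 0.15 ± 0.39 (edgeR adjusted p = 0.994). The nuclear rRNA gene CT010467.1 took 24.1% and 28.5% of counts in SISC and LISC replicate 1, but 0.0917% and 0.0997% in SISC and LISC replicate 2. Mitochondrial rRNA genes took 7.65% and 8.08% in the replicate 1 libraries and 0.154% and 0.204% in the replicate 2 libraries. Ribosomal protein genes went the other way, at 4.39% and 4.25% in replicate 1 and 14.1% and 10.5% in replicate 2. The Wilson 95% intervals of these shares, which cover counting error only, were at most 0.0495 percentage points wide. Libraries therefore differed by replicate number as well as by intestine, and values within each replicate number, which are differences between single libraries with no test, are given for the called genes as a whole, for the gene lists and for some genes.

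**Figure D1:**
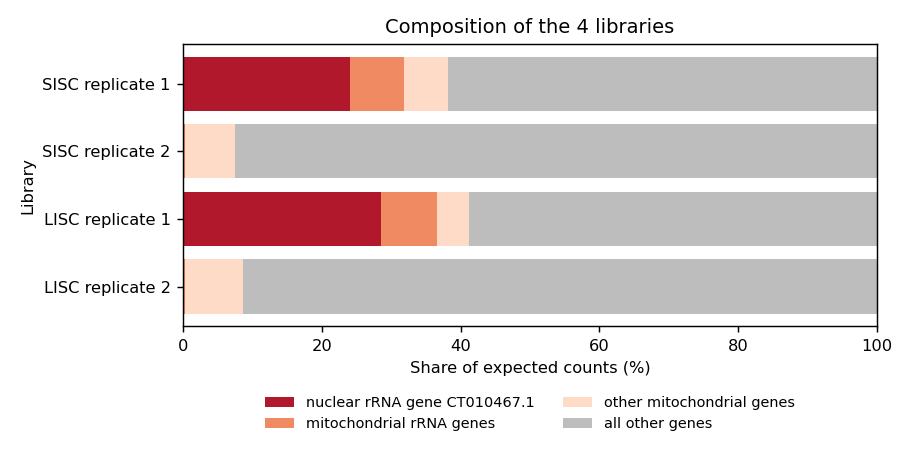
Share of expected counts (percent, horizontal axis) taken by the nuclear rRNA gene CT010467.1, mitochondrial rRNA genes, other mitochondrial genes and all other genes in each of the 4 libraries, 1 stacked bar per library. The nuclear rRNA gene takes 24.1% and 28.5% in the replicate 1 libraries and under 0.1% in the replicate 2 libraries.

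The comparison of LISC with SISC asked which genes, transcription factor genes among them, differ between stem cells of the large and the small intestine. Sult1a1, a cytosolic sulfotransferase, was 581-fold higher in LISC, at 716 ± 404 CPM against 1.21 ± 0.369 CPM in SISC (SD, n = 2 each). Car2, a carbonic anhydrase, was 402-fold higher in LISC, and Hao2, a peroxisomal hydroxy acid oxidase, 556-fold higher (log2 7.07 and 9.92 within replicates 1 and 2). In the other direction, the zinc finger factor gene Gata4 was 1043-fold higher in SISC, with 1 and 3 counts in the LISC libraries. The urea transporter gene Slc14a1 was 215-fold and the secreted Wnt antagonist gene Sfrp5 155-fold higher in SISC. Of 14165 genes tested, 311 were called at an adjusted p below 0.05 by edgeR's quasi-likelihood test, 206 higher in LISC and 105 higher in SISC, and 1899 had an unadjusted p below 0.05. The median fold of the called genes was 24.4 among those higher in LISC and 22.3 among those higher in SISC, and the smallest fold called was 3.07. Each of the 311 differed in the same direction and by at least 2-fold within replicate 1 and within replicate 2. The test that called them used the same libraries, so this is a description and no separate support. The median log2 difference of the genes higher in LISC was 4.27 within replicate 1 and 4.56 within replicate 2, and that of the genes higher in SISC was −4.32 and −4.25. The common biological coefficient of variation was 43.4%. The counts depended on the test: DESeq2 called 769 and 384 genes, edgeR with no filter on low counts called 942 and 465, a test against a fold of 2 called 115 and 55, and leaving out SISC replicate 1 gave 338 and 149.

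Several of the genes with the largest changes had no count in the other group. St3gal5 (ENSMUSG00000056091; chromosome 6, 72097592 to 72154571, GRCm38), the sialyltransferase that makes ganglioside GM3, had 0 counts in both SISC libraries and 57.1 ± 8.59 CPM in LISC, so it was at least 366-fold higher in LISC (edgeR adjusted p = 0.0155). The forkhead factor gene Foxd2 (ENSMUSG00000055210; chromosome 4, 114906282 to 114908873) was at least 322-fold higher in LISC, at 50.3 ± 11.8 CPM (edgeR adjusted p = 0.0168). Gip, the gene of an incretin hormone, and Defa36, an alpha-defensin gene, had 0 counts in LISC and were at least 40.4-fold and at least 934-fold higher in SISC (edgeR adjusted p = 0.0403 and 0.0193). Fa2h, a fatty acid 2-hydroxylase, and St6galnac6, another sialyltransferase, were 241-fold and 202-fold higher in LISC. St6galnac6 had log2 differences of 5.79 and 8.75 within replicates 1 and 2. In the SISC libraries Fa2h had 1 and 5 counts and St6galnac6 had 8 and 2. For genes with 1 to 3 counts in the lower group the ratio of pooled counts is given with its exact 95% interval, which covers counting error only. Anxa1, the annexin A1 gene, was 765-fold higher in LISC (137 to 30270) and the gastrokine gene Gkn3 1706-fold higher in SISC (583 to 8273). C1qa, a complement component gene, was 582-fold higher in LISC (161 to 4809), and its call was lost without SISC replicate 2, where its log2 difference, fitted against 0 counts, was 11.46.

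Hox genes, which encode the homeodomain factors that set position along the body axis, were higher in LISC. Of 16 anterior Hox genes tested (paralog groups 1 to 8), 8 were called higher in LISC and 0 higher in SISC, and 15 were higher when adjusted over the list alone. Hoxb6 (ENSMUSG00000000690; chromosome 11, 96292476 to 96301569) was read at 75.6 ± 3.33 CPM in LISC and 1.54 ± 0.594 CPM in SISC, a log2 difference of 5.65 ± 0.40 (edgeR adjusted p = 0.0167). Hoxb7 was 46.9-fold, Hoxa5 91.7-fold and Hoxd4 104-fold higher in LISC. Hoxa7, with 0 and 23 counts in the SISC libraries, was 141-fold higher, with log2 differences of 9.25 and 6.39 within replicates 1 and 2. Hoxa2, with 1 count in SISC, was 203-fold higher by pooled counts (36.0 to 8065). Of 6 posterior Hox genes tested (paralog groups 9 to 13), 3 were called higher in LISC and all 6 when adjusted over the list alone. Hoxa10 (ENSMUSG00000000938; chromosome 6, 52231197 to 52240854) was read at 27.2 ± 7.58 CPM in LISC and 0.135 ± 0.0145 CPM in SISC, a log2 difference of 7.63 ± 0.44 (edgeR adjusted p = 0.0155). Hoxa10 had 2 and 4 counts in the SISC libraries, so its SISC SD does not cover counting error. Hoxa11 was at least 26.6-fold higher in LISC. Hoxa9, with 0 and 13 counts in the SISC libraries, was 174-fold higher, with log2 differences of 8.87 and 6.58 within replicates 1 and 2. Without SISC replicate 2 the SISC count of Hoxa7 and Hoxa9 is 0, so their folds rest on that library. Hoxb13 and Hoxa13, at 5.68 ± 3.97 and 3.56 ± 2.16 CPM in LISC and 0 counts in SISC, missed the threshold (edgeR adjusted p = 0.0664 and 0.0753), as did Hoxb9, at 68.1 ± 11.6 CPM in LISC and 1.03 ± 1.11 CPM in SISC (0.0546). The anterior list had a median log2 difference of 5.60, or 5.37 with genes at 0 counts set to their bound, and 4.94 and 4.95 within replicates 1 and 2. For the posterior list these values were 8.45, or 5.69 at the bound, and 5.13 and 6.55. The posterior median was 4.82 with DESeq2 and 5.39 with no filter on low counts, and limma-trend on TPM gave 3.02 and 3.999 for the anterior and posterior lists. Both lists were called by limma's camera (adjusted p = 5.25e-20 and 9.70e-10), but not with an estimated correlation between genes (adjusted p = 0.170 and 0.297 with an estimated correlation). The antisense transcript gene Hoxa11os (chromosome 6, 52244393 to 52249799, plus strand) was at least 98.0-fold higher in LISC. It overlaps part of Hoxa11 (52242106 to 52245810, minus strand), and the strand setting of the counting is not given in the sources used here. Reads of the pair within the shared stretch therefore cannot be told apart. The calls of Hoxa11 and Hoxa2 were lost without SISC replicate 2 (log2 9.22 and 9.52, fitted against 0 counts), that of Hoxa11 also without LISC replicate 2 (9.06) and that of Hoxa2 without LISC replicate 1 (7.16). The call of Hoxa7 was lost with DESeq2's size factors (7.11).

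Of 14 factor genes known from the proximal intestine, 3 were called, each higher in SISC, and 9 were higher in SISC when adjusted over the list alone. Gata4 (ENSMUSG00000021944; chromosome 14, 63198922 to 63271692) was read at 110 ± 30.5 CPM in SISC and 0.0979 ± 0.00739 CPM in LISC, a log2 difference of −10.03 ± 0.49 (edgeR adjusted p = 0.0155), and of −9.47 and −8.82 within replicates 1 and 2. Gata4 had 1 and 3 counts in the LISC libraries, so its LISC SD does not cover counting error. The cut-domain factor gene Onecut2 (chromosome 18, 64340020 to 64400987) was 535-fold and Gata5 (chromosome 2, 180325133 to 180334699) 24.6-fold higher in SISC. Onecut2 had 0 and 6 counts in the LISC libraries and log2 differences of −9.48 and −8.24 within replicates 1 and 2, and its fold rests on LISC replicate 2, without which the LISC count is 0. Pdx1, a homeobox factor gene of pancreas and duodenum, had 6.54 ± 0.728 CPM in SISC and 0.0687 ± 0.0972 CPM in LISC and missed the threshold (edgeR adjusted p = 0.0546). The list's median log2 difference was −2.70, or −2.003 at the bound, and −2.29 and −2.04 within replicates 1 and 2; it was −1.21 without SISC replicate 2, −1.73 with DESeq2, −0.96 with limma-trend and −0.94 with a stricter filter. Camera called it (adjusted p = 1.85e-08; adjusted p = 0.297 with an estimated correlation). None of 16 factor genes used along the whole intestine was called, also when adjusted over the list alone, with log2 differences of 0.57 ± 0.29 for Cdx1, 0.60 ± 0.29 for Cdx2 and −0.94 ± 0.39 for Hnf4a. That list's median was 0.39, and 0.30 and 0.37 within replicates 1 and 2, and camera did not call it (adjusted p = 0.398). It was 0.17 without SISC replicate 2 and 0.22 without LISC replicate 1.

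Across all 721 transcription factor genes tested, 27 were called, 21 higher in LISC and 6 higher in SISC. This was 3.74% of them against 2.11% of the other genes tested (odds ratio 1.80, two-sided Fisher's exact p = 0.00598; genes are not independent replicates). Among Hox genes 11 of 22 were called, and of the other 699 factor genes 16, or 2.29% (odds ratio 1.09, two-sided Fisher's exact p = 0.687). Of these, factor genes without a zinc finger symbol were called in 14 of 309 cases (4.53%, odds ratio 2.20, Fisher's exact p = 0.00865) and those with one in 2 of 390 (0.513%, odds ratio 0.239, p = 0.0275). The tests of these parts were chosen after the data were seen. Besides Foxd2 and 11 Hox genes, the nuclear receptor gene Pparg was 15.9-fold and the ETS factor gene Etv5 11.7-fold higher in LISC. Besides the 3 proximal genes, the homeobox gene Pitx1 was 24.4-fold, the Wnt target gene Sp5 5.17-fold and the zinc finger gene Zfp503 4.09-fold higher in SISC. Zfp503 lost its call under 7 of the 12 alternatives run on it, its log2 difference staying between −2.28 and −1.53. DESeq2 called 82 factor genes.

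**Figure D2:**
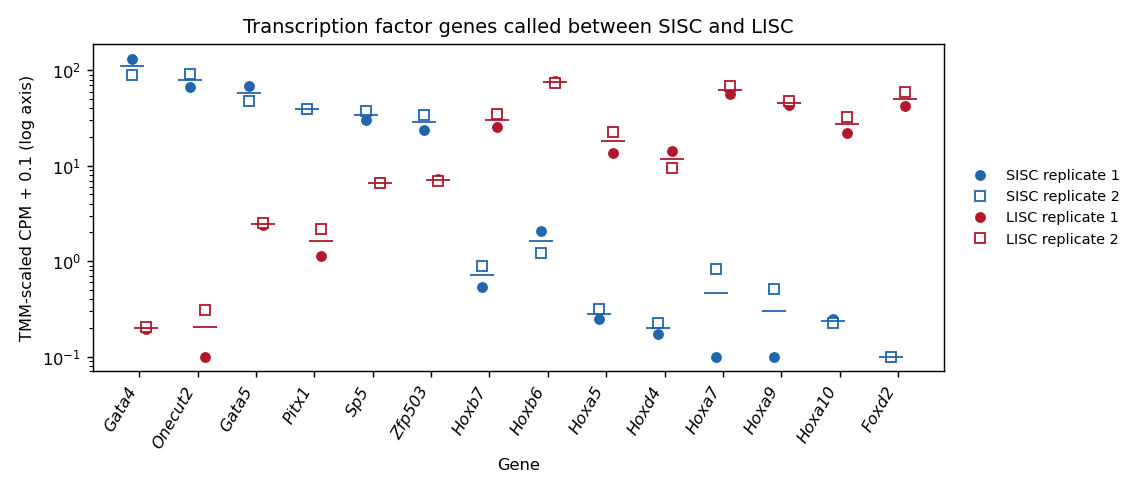
TMM-scaled CPM plus 0.1 (logarithmic vertical axis) of 14 transcription factor genes called between the groups, for each SISC (blue) and LISC (red) library. Filled circles are replicate 1, open squares replicate 2 and short lines group means. For each gene drawn, both libraries of one group lie above both of the other, for example 88.8 and 132 CPM in SISC for Gata4.

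Called genes of the differentiated epithelium of each intestine followed the same division. Of 22 large-intestinal epithelial genes tested, 8 were called higher in LISC and 0 higher in SISC. Adjusted over the list alone, the counts were 15 and 2. Cyp2c55, a cytochrome P450, was 91.3-fold higher in LISC, at 217 ± 118 CPM against 2.33 ± 1.13 CPM (SD, n = 2 each). Among the called genes 3 were gasdermin C genes, with Gsdmc2 44.9-fold, Gsdmc4 39.9-fold and Gsdmc3 24.4-fold higher. Car4, a membrane carbonic anhydrase, was 17.0-fold and Scnn1a, a subunit of the epithelial sodium channel, 9.42-fold higher. Car1, with 126 and 920 CPM in LISC and 0 counts in SISC, missed the threshold (edgeR adjusted p = 0.0603). The list's median log2 difference was 4.31, or 3.61 at the bound, and 3.34 and 4.14 within replicates 1 and 2 (camera adjusted p = 1.05e-09; adjusted p = 0.415 with an estimated correlation). Of 28 small-intestinal absorptive genes tested, 5 were called higher in SISC and 0 higher in LISC. Adjusted over the list alone, the counts were 15 and 1. Mttp, which loads lipid onto apolipoprotein B, was read at 78.7 ± 4.55 CPM in SISC and 2.93 ± 1.26 CPM in LISC, a 26.2-fold difference (edgeR adjusted p = 0.0202). The apolipoprotein gene Apoa4 was at least 63.3-fold, the sucrase-isomaltase gene Sis 28.7-fold and the alcohol dehydrogenase gene Adh6a 17.1-fold higher in SISC. The median log2 difference of the absorptive list was −2.02, and −2.18 and −1.65 within replicates 1 and 2 (camera adjusted p = 7.28e-15; adjusted p = 0.170 with an estimated correlation). The calls of Gsdmc2 and Gsdmc4 were lost without SISC replicate 2 (log2 5.13 and 4.89). Gasdermin C and Cyp2c genes have close copies, among which the counting may have divided reads, so their values are uncertain.

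Among stem cell markers, Olfm4 had the largest difference. It was read at 10118 ± 3328 CPM in SISC and 99.7 ± 11.7 CPM in LISC (SD, n = 2 each), a 101-fold difference (edgeR adjusted p = 0.0269). Tnfrsf19, a receptor gene of the Lgr5 stem cell signature, was 9.04-fold and Igfbp4, a binding protein of insulin-like growth factors, 7.17-fold higher in SISC. These 3 of 26 stem cell markers were called, all higher in SISC, and 8 were when adjusted over the list alone. Ascl2, the stem cell factor gene, differed by −0.36 ± 0.30 on the log2 scale and Smoc2 by −1.40 ± 0.37, neither past the threshold (edgeR adjusted p = 0.819 and 0.172). The median log2 difference of the list was −0.43, and −0.24 and −0.71 within replicates 1 and 2 (camera adjusted p = 3.44e-06; adjusted p = 0.415 with an estimated correlation). The calls of Olfm4 and Igfbp4 were lost without LISC replicate 1 (log2 −6.55 and −2.97) and without LISC replicate 2 (−6.78 and −2.71), and that of Tnfrsf19 without LISC replicate 2 (−2.91).

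Of 19 Wnt pathway genes tested, Tcf7l1, a repressor of Wnt target genes, was 39.0-fold higher in LISC and Sp5 higher in SISC. Adjusted over the list alone, 2 were higher in LISC and 3 in SISC. The Wnt target gene Axin2 was read at 292 ± 3.55 CPM in SISC and 110 ± 18.6 CPM in LISC and did not pass (edgeR adjusted p = 0.119). The list's median log2 difference was −0.33, and −0.38 and −0.52 within replicates 1 and 2 (camera adjusted p = 0.0204; adjusted p = 0.592 with an estimated correlation). Its camera call was lost without SISC replicate 1 (median −0.46) and without LISC replicate 2 (−0.31), and its median was −0.60 without LISC replicate 1. The call of Tcf7l1 was lost without SISC replicate 2 (log2 4.56) and without LISC replicate 2 (4.71), and that of Sp5 without LISC replicate 1 (−2.38) or LISC replicate 2 (−2.35). None of 17 Notch pathway genes was called, also when adjusted over the list alone (median 0.12, and 0.05 and 0.26 within replicates 1 and 2; camera adjusted p = 0.750). That median was 0.36 and −0.09 without SISC replicates 1 and 2 and −0.07 and 0.39 without LISC replicates 1 and 2, so its sign depends on single libraries. The proliferation gene Mki67 differed by −0.01 ± 0.90, and by −1.14 to 1.31 over its alternatives, so its sign is open. None of 30 proliferation genes was called, also when adjusted over the list alone. Their median log2 difference was −0.33, with 28 of the 30 below 0 (camera adjusted p = 0.00312; adjusted p = 0.297 with an estimated correlation), and −0.25 and −0.34 within replicates 1 and 2. That camera call was lost without LISC replicate 2 (median −0.29).

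Of 23 Paneth cell markers tested, 4 were called higher in SISC and 0 higher in LISC, and 18 and 2 when adjusted over the list alone. The other way went Mptx1, a pentraxin gene, with 13.2 and 186 CPM in LISC and 0.146 and 0.219 CPM in SISC (edgeR adjusted p = 0.0847). All 4 were genes of the alpha-defensin cluster on chromosome 8: Defa30 was 369-fold, Defa5 223-fold and AY761184 653-fold higher in SISC, and Defa26, with 1 count in LISC, 463-fold by pooled counts (82.7 to 18320). Reads of these near-identical genes may have been divided among copies by the counting, so each gene's value is uncertain. Outside the family, the lysozyme gene Lyz1 had 4147 and 445 CPM in SISC and 22.8 and 1.92 CPM in LISC, and the lectin gene Itln1 had 1863 and 241 CPM in SISC and 7.88 and 3.82 CPM in LISC (edgeR adjusted p = 0.158 and 0.0730). The median log2 difference of the Paneth list was −7.05, and −6.91 and −6.44 within replicates 1 and 2 (camera adjusted p = 7.04e-12; adjusted p = 0.415 with an estimated correlation). The calls of Defa5, Defa26, Defa30 and AY761184 were lost when rRNA and mitochondrial genes were left out, an alternative chosen after seeing the data, with log2 differences of −7.81, −8.73, −8.52 and −9.35.

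None of the 17 tuft cell markers was called over all genes, but 13 were higher in LISC when adjusted over the list alone. All 17 lay above 0, with 2.00 ± 2.52 CPM in SISC and 31.6 ± 14.2 CPM in LISC for the kinase gene Dclk1 and 4.38 ± 4.51 and 32.4 ± 4.54 CPM for the taste channel gene Trpm5 (edgeR adjusted p = 0.234 and 0.224). The tuft list's median log2 difference was 3.56 (1.74 with limma-trend), and 1.93 and 5.09 within replicates 1 and 2 (camera adjusted p = 2.29e-10; adjusted p = 0.415 with an estimated correlation). Of 25 goblet and deep crypt secretory markers, 0 were called, and 7 were higher in LISC when adjusted over the list alone. Reg4 had 88.4 and 17.9 CPM in SISC and 617 and 2796 CPM in LISC, and the mucin gene Muc2 358 and 17.1 CPM in SISC and 1045 and 1147 CPM in LISC (edgeR adjusted p = 0.147 and 0.578). This list's median was 1.98 (3.18 without SISC replicate 1), and 1.02 and 3.64 within replicates 1 and 2 (camera adjusted p = 3.18e-08; adjusted p = 0.467 with an estimated correlation). Of 20 enteroendocrine markers, the hormone gene Sct was 24.4-fold higher in LISC and Gip higher in SISC, and 2 and 1 were higher in LISC and SISC when adjusted over the list alone. The enteroendocrine median was −0.76 (camera adjusted p = 0.713), and −1.25 and 0.78 within replicates 1 and 2. It was 0.96 without SISC replicate 1 and −1.81 without SISC replicate 2, and camera called each of these. The call of Sct was also lost without SISC replicate 2 (log2 4.21). Of the 30 immune cell markers, 8 could be tested, and C1qa was the one called, also when adjusted over the list alone (median 0.39, and 0.21 and 0.59 within replicates 1 and 2; camera adjusted p = 0.455). The immune median was −0.17 without SISC replicate 1, 1.63 without SISC replicate 2 and −0.82 without LISC replicate 2. Only 4 of 24 stromal, endothelial and glial markers passed the filter, too few for a list test, and their median was 0.41.

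All 24 dissociation stress and immediate early genes lay below 0, with a median log2 difference of −1.36, although 0 were called, also when adjusted over the list alone. Atf3 had 566 and 92.1 CPM in SISC and 11.03 and 24.9 CPM in LISC, and Egr1 1086 and 402 CPM in SISC and 192 and 101 CPM in LISC (edgeR adjusted p = 0.150 and 0.197). Without SISC replicate 1 the median was −0.76, and within replicates 1 and 2 it was −1.52 and −0.94 (camera adjusted p = 4.06e-09; adjusted p = 0.415 with an estimated correlation). These genes took 1.16% and 1.06% of all counts in the SISC libraries and 0.440% and 0.691% in the LISC libraries. The nuclear rRNA gene took 24.1% and 28.5% of counts in SISC and LISC replicate 1, and 0.0917% and 0.0997% in replicate 2. That lowers the replicate 1 shares, so the shares cannot be compared between replicate numbers.

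Most called genes of the detoxification and transport lists were higher in LISC, as were 206 of all 311 called genes. Of 29 retinoid and xenobiotic metabolism genes tested, 6 were called higher in LISC and 1 higher in SISC, and 10 and 3 when adjusted over the list alone. The carboxylesterase gene Ces1f was read at 146 ± 7.53 CPM in LISC and 2.41 ± 0.430 CPM in SISC, a 60.02-fold difference (edgeR adjusted p = 0.0155). Aldh1a1, a retinaldehyde dehydrogenase, was 11.5-fold and Abcb1a, a drug efflux pump, 10.2-fold higher in LISC, while Abcc2, an efflux pump for conjugates, was 45.2-fold higher in SISC. The list's median log2 difference was 0.67, and 0.57 and 0.92 within replicates 1 and 2 (camera adjusted p = 0.00875; adjusted p = 0.652 with an estimated correlation). Of 29 ion, water and bile salt transport genes, Hsd11b2, which inactivates glucocorticoids beside the mineralocorticoid receptor, was 29.5-fold and Slc5a8, a short-chain fatty acid transporter, 22.9-fold higher in LISC. Those 2 were the ones called, and 9 were higher in LISC and 1 in SISC when adjusted over the list alone. The transport list's median was 0.27 (0.51 without SISC replicate 1, 0.46 without SISC replicate 2 and up to 0.56 over its alternatives), and 0.24 and 0.40 within replicates 1 and 2 (camera adjusted p = 0.00507; adjusted p = 0.297 with an estimated correlation). Of 29 genes of fatty acid oxidation and ketogenesis, Pparg, which encodes a lipid-sensing receptor rather than an enzyme, was the one called, and 4 were higher in LISC and 1 in SISC when adjusted over the list alone. This list's median was 0.31, and 0.17 and 0.47 within replicates 1 and 2 (camera adjusted p = 0.0202; adjusted p = 0.659 with an estimated correlation). None of 24 cholesterol synthesis genes was called, also when adjusted over the list alone (median 0.28, and 0.01 and 0.48 within replicates 1 and 2; camera adjusted p = 0.168). Camera called that list without LISC replicate 1 (median 0.44), and its median was 0.04 without LISC replicate 2. The calls of Aldh1a1 and Abcb1a were lost without SISC replicate 2 (log2 3.18 and 3.33). Camera's calls for the retinoid and fatty acid lists were lost without SISC replicate 1 (medians 0.51 and 0.27) and without LISC replicate 2 (0.08 and 0.19).

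Several genes of MHC class II, which presents antigen to helper T cells, were called higher in SISC. H2-Eb1 was read at 109 ± 5.49 CPM in SISC and 16.7 ± 1.08 CPM in LISC, a 6.53-fold difference (edgeR adjusted p = 0.0227), and the invariant chain gene Cd74 was 6.14-fold, H2-Aa 5.32-fold and H2-Ab1 4.80-fold higher in SISC. With H2-DMa these made 5 called genes, all higher in SISC, of 30 MHC class II and interferon-responsive genes tested, and 9 were higher in SISC when adjusted over the list alone. The list's median log2 difference was −0.27, and −0.43 and −0.18 within replicates 1 and 2 (camera adjusted p = 0.00507; adjusted p = 0.448 with an estimated correlation). Its camera call was lost without LISC replicate 1 (median −0.20) and without SISC replicate 1, where the median was 0.23; without SISC replicate 2 the median was −0.42. Of 22 epithelial host-defence genes, Wfdc2, a secreted protease inhibitor, was 16.4-fold and the NADPH oxidase gene Nox1 11.2-fold higher in LISC, and the chemokine gene Ccl25 was 14.9-fold and the nitric oxide synthase gene Nos2 7.26-fold higher in SISC. Adjusted over the list alone, 4 were higher in LISC and 6 in SISC. The median of the host-defence list was 0.08 (0.13 and 0.09 within replicates 1 and 2, −0.03 without SISC replicate 1 and 0.02 without LISC replicate 1), its mean −0.02 and camera's direction lower in LISC, with no call (adjusted p = 0.689). Reg3b and Reg3g, which encode antibacterial lectins, had 209 ± 83.9 and 174 ± 45.4 CPM in SISC and 27.8 ± 15.9 and 25.6 ± 18.5 CPM in LISC and did not pass (edgeR adjusted p = 0.0944 and 0.126). The calls of Cd74 and H2-Ab1 were each lost without SISC replicate 2 (log2 −2.45 and −2.19), LISC replicate 1 (−2.49 and −2.30) and LISC replicate 2 (−2.75 and −2.21). The same held for H2-Eb1 (−2.64 and −2.76) and Ccl25 (−3.92 and −3.86) without LISC replicate 1 and without LISC replicate 2, for H2-Aa without LISC replicate 2 (−2.22), and for Nos2 without SISC replicate 2 (−2.84) and without LISC replicate 2 (−2.67).

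Without 1 library the folds of several called genes moved by over 1.5 times. Their log2 differences then ran from 8.46 to 9.67 for Sult1a1, 8.11 to 10.31 for Hao2, 7.63 to 8.63 for Fa2h, 6.44 to 9.59 for St6galnac6, 5.81 to 7.11 for Cyp2c55, 4.52 to 6.07 for Gsdmc2, 4.34 to 5.90 for Gsdmc4, 4.01 to 5.03 for Gsdmc3, 4.56 to 6.09 for Tcf7l1, 3.74 to 5.14 for Sct and 4.27 to 5.84 for Hsd11b2. Among genes higher in SISC they ran from −5.45 to −3.89 for Sis, −5.25 to −4.25 for Pitx1, −4.42 to −3.10 for Ccl25, −10.29 to −7.65 for AY761184, −9.85 to −7.50 for Defa30 and −8.52 to −6.45 for Defa5. They ran from −11.37 to −8.98 for Gkn3, which had 42.4 and 165 CPM in the SISC libraries. For Anxa1 and C1qa, higher in LISC, they ran from 7.55 to 11.51 and from 7.32 to 11.46. The upper value of each was fitted against 0 counts in SISC.

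Some of these calls also ended under other settings, with the direction kept. With DESeq2's size factors in the edgeR fit these were AY761184 (log2 −9.38), Defa30 (−8.55), C1qa (8.65), Hoxa11 (9.47), Gsdmc4 (5.27), Tcf7l1 (5.25) and Ccl25 (−3.92). Without rRNA and mitochondrial genes they were C1qa (8.69), Hoxa11 (9.49), Hoxa7 (7.16), Gsdmc4 (5.30), Tcf7l1 (5.28), Sis (−4.85), Sct (4.60), Hsd11b2 (4.88) and Ccl25 (−3.87). With limma-trend on log2(TPM + 1) they were Hoxa11 (1.53), Hoxa2 (1.91), Igfbp4 (−2.75), Sp5 (−2.07), Nos2 (−1.62), H2-Eb1 (−2.73), Cd74 (−2.66), H2-Aa (−2.41) and H2-Ab1 (−2.28). That scale understates the change of low genes such as Hoxa11 and Hoxa2. The differences of H2-Eb1, Cd74, H2-Aa and H2-Ab1 kept their size but not their calls. Their limma-trend adjusted p ran from 0.168 (H2-Eb1) to 0.548 (H2-Ab1). Camera's calls were lost for the Wnt list with limma-trend (median −0.34) and for the fatty acid list with no filter on low counts (0.29).

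Genes given above as missing the threshold were in part called by other tests, in the same direction. DESeq2 called Hoxb13, Hoxa13, Hoxb9, Pdx1, Car1, Smoc2, Axin2, Lyz1, Itln1, Mptx1, Dclk1, Trpm5, Reg4, Atf3, Egr1, Reg3b and Reg3g, with adjusted p from 1.07e-17 (Itln1) to 0.00800 (Smoc2). EdgeR with no filter on low counts called each of these and Muc2, and limma-trend called Hoxb9, Car1, Lyz1, Itln1, Mptx1, Dclk1, Trpm5, Reg4 and Atf3. The block on replicate number, a pairing that the labels do not state, called those named for DESeq2 except Dclk1, Reg4 and Atf3. The block also called Hnf4a (log2 −0.92) and, of the dissociation stress list, Fos (−1.42). Without SISC replicate 1, edgeR called Hoxb13, Hoxa13, Car1, Hoxb9 (log2 8.05), Pdx1 (−5.99), Itln1 (−5.39), Dclk1 (7.14), Trpm5 (4.76) and Muc2 (6.00), and without SISC replicate 2 Hoxb9 (5.20), Itln1 (−8.34) and Atf3 (−5.01). Without LISC replicate 1 it called Hoxb13, Hoxa13, Car1, Hoxb9 (6.35), Pdx1 (−5.52), Lyz1 (−10.21), Mptx1 (9.88) and Reg4 (5.72), and without LISC replicate 2 Car1, Hoxb9 (6.00), Pdx1 (−9.94) and Mptx1 (6.08).

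Of the 24 lists, 23 were tested, and camera called 16 with its preset correlation, 8 higher and 8 lower in LISC. With a correlation estimated from the 4 libraries it called 0, but its degrees of freedom then come from the 4 libraries, which leaves little power. The rotation test fry, which asks whether a list's genes move one way on balance, called 5. These were the anterior Hox, posterior Hox, proximal factor, absorptive and ion, water and bile salt transport genes. Its mixed form, in which genes of a list may move either way, called 17. Among these were lists that camera did not call: pan-intestinal factors, host-defence genes and enteroendocrine markers (fry mixed adjusted p = 0.00409, 0.00334 and 0.00302). Of the 5 sex-linked genes tested 0 were called, also when adjusted over the list alone, and their median (0.69), mean (−1.01) and camera direction (higher in LISC, adjusted p = 0.398) differed in sign. Within replicates 1 and 2 their median was 8.10 and 0.08, and camera called them without SISC replicate 2 (median 12.18, adjusted p = 0.000569) but not without SISC replicate 1 (−0.30, adjusted p = 0.710).

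**Figure D3:**
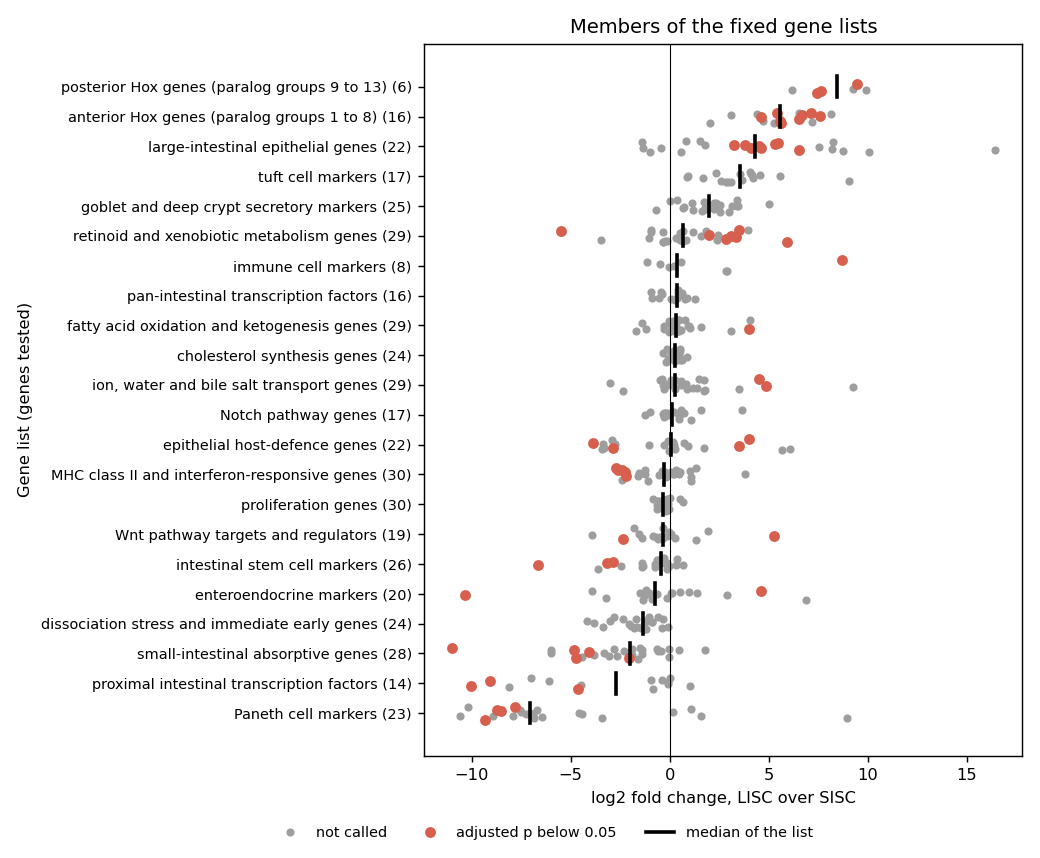
Log2 fold change of LISC over SISC (horizontal axis) of each tested member of 22 gene lists, 1 list per row with the number of genes tested in brackets. Red points are genes with an edgeR adjusted p below 0.05, grey points other genes and black bars the list medians, which run from −7.05 for Paneth cell markers to 8.45 for posterior Hox genes; points of genes with 0 counts in a group are fitted values, not bounds.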

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

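Leaving out rRNA and mitochondrial genes was chosen only after the data were seen; the other alternatives were planned. The 206 genes higher in LISC, 105 higher in SISC and 27 transcription factor genes became 769, 384 and 82 with DESeq2 and 942, 465 and 92 with no filter on low counts, and the cause was not tested. A test against a fold of 2 gave 115 and 55, as its stricter hypothesis must. The replicate block, which treats the replicate number as a pair, gave 1015, 524 and 92, and the Wnt list's camera call was not made (median −0.34, adjusted p = 0.0518). The labels do not say that the numbers pair the samples, and with only 2 numbers this is open, although deviations from the group means correlated at 0.648 across genes between libraries of the same number. Leaving out 1 library, which leaves its group with a lone sample assumed to vary like the other group, gave 166 to 338 genes higher in LISC (338 without SISC replicate 1), 79 to 149 higher in SISC, 27 to 40 factor genes and 12 to 18 lists called. Of the 311 genes, the calls kept were 311 with DESeq2, with no filter, with the stricter filter and with the block, 309 with upper-quartile factors, 272 with DESeq2's size factors, 240 without rRNA and mitochondrial genes, 180 with limma-trend on TPM, and 276, 219, 243 and 205 without SISC replicate 1, SISC replicate 2, LISC replicate 1 and LISC replicate 2; no gene among them changed direction. The share of calls higher in LISC was 66.2% and ran from 57.7% to 70.2%. The 16 lists called by camera fell to 0 with an estimated correlation. That estimate lay below the preset of 0.01 for the anterior Hox (−0.0648), absorptive (0.00942), proliferation (−0.0227) and transport lists (−0.0294). A raised correlation therefore cannot be why these lists lost their calls. For the other called lists the estimate ran from 0.105 to 0.668. With an estimated correlation camera also takes its degrees of freedom from the 4 libraries and not from the genes. In the simulation the camera p of a raised list of randomly picked genes likewise went from 6.06e-14 to 0.0146. The loss of a call is therefore no evidence that a list did not move. Without SISC replicate 1 the enteroendocrine median became 0.96 (adjusted p = 0.00427; 4.67e-06 to 0.920 over its alternatives) and that of the MHC class II and interferon list 0.23. Leaving out 1 library gave medians from −1.81 to 0.96 and from −0.42 to 0.23 for these lists, and the cause was not tested. Genes called by edgeR differed by at least 3.07-fold. In the simulation with the real difference between replicate numbers edgeR recovered 0% of changes up to 16-fold. That simulation gave both groups the same difference between replicate numbers, while the real data gave 311 calls, so 0% is not their recovery. A gene without a call is still not shown to be unchanged.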

Other observations

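All tests in this part were chosen after the data were seen. Of 72 glycan transferase genes, a set of 13 symbol prefixes put together by hand after its genes were seen and so not tested, 10 were called higher in LISC and 0 higher in SISC. Next to St3gal5 and St6galnac6 they included B3galt5, a galactosyltransferase gene 110-fold higher in LISC, the sulfotransferase gene Chst4, 23.0-fold higher, and Gcnt3, which branches mucin glycans, 20.1-fold higher, with log2 differences without 1 library from 5.80 to 7.34, 3.99 to 5.17 and 3.71 to 5.31. The call of Gcnt3 was lost with DESeq2's size factors (log2 4.29) and without rRNA and mitochondrial genes (4.33), with adjusted p from 3.90e-18 to 0.0611 over its alternatives. Among 146 symbol families with at least 10 tested genes, tested in each direction (292 one-sided Fisher's exact tests, adjusted by Benjamini-Hochberg), 9 tests passed 0.05, 3 of them for Hox and alpha-defensin genes. Hydroxysteroid dehydrogenase genes were higher in LISC in 4 of 12 cases (odds ratio 34.5, adjusted Fisher's exact p = 0.00191), with Hsd3b3 61.1-fold higher (log2 5.37 to 6.55 without 1 library), though close copies make each value uncertain. Solute carrier genes went both ways, with 13 of 241 higher in LISC and 9 higher in SISC (odds ratios 4.06 and 5.59, adjusted Fisher's exact p = 0.00381 and 0.00437), and the zinc transporter gene Slc30a2 was higher in SISC (log2 −3.70 ± 0.35). UDP-glucuronosyltransferase (3 of 13), cytochrome P450 (4 of 32) and aldehyde dehydrogenase genes (3 of 16) were also called more often higher in LISC (adjusted Fisher's exact p = 0.0325, 0.0414 and 0.0479). Genes of a family share regulation and sequence, so these p-values are descriptive.

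C1qa was higher in LISC. Its transcripts may come from macrophages in the large-intestinal sort, but C1qb and C1qc, which macrophages transcribe with it, had 0 counts over all 4 libraries against 1014 counts of C1qa in LISC, which argues against that source. Reads of an overlapping gene are argued against by the annotation, where 0 other genes overlap C1qa. Expression in the large-intestinal stem cells themselves, or a difference between the sorts, stays open and was not tested.

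Tuft and goblet markers had positive medians in LISC. A lower share of stem cells in the LISC sort may raise markers of all other crypt cells alike. The tuft median exceeded the enteroendocrine median by 4.32 on the log2 scale (17 and 20 genes). This gap was 3.19 and 4.31 within replicates 1 and 2 and 3.73 to 4.53 without 1 library. It cannot decide, as enteroendocrine genes may differ between the intestines by themselves: Gip had 0 counts in LISC, and Sct was 24.4-fold higher there. What goes with a lower share is that 23 of 26 stem cell markers lay below 0 (median −0.43). These markers too may differ between the intestines by themselves. Olfm4 was 101-fold higher in SISC, while the log2 difference of Lgr5 was −0.28 ± 0.40 (SE). The enteroendocrine median was also 0.96 without SISC replicate 1, so a lower share of stem cells stays open. CD24-positive cells kept by the LISC gate, which named no CD24 exclusion, are another candidate explanation. Cd24a differed by 0.153 (SE 0.385), which decides nothing, so the gate cannot be told apart from a difference between the tissues.

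Of 23 Paneth markers 19 lay below 0, with 4 called higher in SISC and, outside the defensin family, 7 below and 4 above 0 (median −4.43), although the SISC gate excluded CD24-positive cells and Paneth cells are known to carry CD24. Division of reads among defensin copies leaves the family's sum as it is, and CPM summed over all 18 tested alpha-defensin genes was 4.62 log2 units higher in the lower SISC library than in the higher LISC library, which argues against that source of the defensin difference. Paneth cells or their free RNA in the SISC sort may be the source. The ratio of SISC replicate 1 to replicate 2 would then be alike over the 19 lower markers. Its SD on the log2 scale was 0.732, at percentile 16.4 of 10000 random sets matched on expression, which is inconclusive. The median of that log2 ratio was 2.73. Goblet (0.238% and 0.0834%), enteroendocrine (0.0194% and 0.00603%) and tuft markers (0.00383% and 0.00243%) also took more counts in SISC replicate 1 than in replicate 2. Absorptive genes took 0.203% and 0.211%. These are shares of all counts, and rRNA lowers them in SISC replicate 1. The nuclear rRNA gene took 24.1% of counts there and 0.0917% in SISC replicate 2. The absorptive shares therefore do not show that these genes were not raised in replicate 1. Paneth RNA in the sort and transcription by the small-intestinal stem cells cannot be told apart here.

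Xist had 7409 counts in SISC replicate 1 and 26, 8 and 10 in SISC replicate 2 and LISC replicates 1 and 2, while the Y-linked gene Ddx3y had 0 counts in SISC replicate 1 and 1302, 278 and 1135 in the others. These are the values of a female animal in SISC replicate 1 and of male animals in the other 3 libraries, so sex differs within SISC and is in part mixed with the groups. Without SISC replicate 1, which leaves libraries of 1 sex, 276 of the 311 calls were kept.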
